A study of Halobacterium salinarum NRC-1 with 42 samples.

How the data were processed

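RNA of the VNG1451C deletion strain and of the ura3 parent was hybridised to spotted oligonucleotide arrays with 10752 spots, each against a common reference of mid log wild type NRC-1. Growth phases and optical densities come from the labels' growth protocols, and a sample whose title carries no replicate number was numbered 1. Per the labels, the sample was in Alexa 547 and the reference in Alexa 647 on 21 arrays and the other way round on the 21 flipped arrays; the file headers name the first dye Alexa546. Per the file headers, the per-array files hold spot and local background intensity of both dyes at a bright and a dim scan setting, with no background removed. The deposited value table holds a log10 ratio per spot, whose normalization is not given in the sources used here. No column of other samples was present in it.

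The spot number in the per-array files did not match the row of the value table (correlation of log ratios at most 0.116 on any array). The grid position, ordered by row over 168 rows and 64 columns, did: the correlation was 0.142 to 0.935 with a median of 0.756, over spots at least 100 above background in both dyes. That order was chosen by this match. The slope against the scanner log10 ratio was 0.211 to 1.11, so the table's direction is Alexa 547 over Alexa 647, not turned on flipped arrays, while its scale and its centring stay unknown. Column medians ran from -0.145 to 0.433 with a median of 0, and 0.0279% to 56.6% of a column's values were exactly 0.

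Each gene was spotted 4 times, which gives 2688 features. The platform annotation used here pairs 532 spots with 1 gene symbol, none with several, and leaves 10220 spots unnamed, so 133 features have a name and 2555 are given by the number of their first spot. Which unnamed features are controls was not known, and all were kept. The gene table of another strain's assembly was not used.

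Median foreground per array was 235 to 1728 in Alexa 547 and 396 to 1512 in Alexa 647, over median backgrounds of 30 to 1499 and 18 to 1452. Between 61.3% and 100.0% of spots exceeded their background in Alexa 547 and between 54.0% and 99.9% in Alexa 647. Between 4 and 76 spots per array and channel were saturated. Among named genes, csg was saturated on every array of 4 groups, and gatC and htr18 were not above background on any array of at least 1 group; no value is given for them, although they stay in the counts and the list tests.

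Among arrays of 1 dye orientation, 1 of 420 pairs correlated below -0.3 over all features, the flipped arrays of parent mid log replicate 1 and parent stationary replicate 2 at -0.307. The labels state the dyes and the direction was kept. Dye pairs of the same extract correlated at -0.320 to 0.834 over all features outside the doubted extract (median 0.365), and at 0.291 to 0.907 over the brighter features. A second pair below -0.3, deletion mid log replicate 2 at -0.320, had 0.542 over the brighter features.

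The bright scans were corrected with normexp (offset 50) and normalized by loess within each array in limma 3.58.1 under R 4.3.3. Ratios were turned to sample over reference, the 4 spots of a feature were averaged, and then the 2 arrays of each extract. A model with 1 mean for each of the 8 groups and no replicate block was fitted to the 21 extracts (13 residual degrees of freedom), with moderated statistics from lmFit and eBayes. Two-sided contrasts were called at a Benjamini-Hochberg adjusted p under 0.05. With the replicate number as a block more features passed in each strain comparison, as given under the processing. In simulated data of 2688 features with the residual spread of the real ones, the averaged strain contrast recovered 85.1% of features changed by 0.5 log2 units and 98.5% of those changed by 1. There were 18 false calls among the unchanged features, beside 57, 66 and 66 features recovered at changes of 0.5, 1 and 2. In this 1 simulation the false share of the calls was thus above the threshold of 0.05. The noise was drawn independently for each extract and the same change was added in all phases, so recovery in the real data can be lower. The mid log contrast recovered 32.8% and 86.6%, with 8 false calls.

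Comparisons, alternatives and gene lists were set before the data were examined. For the averaged strain contrast the rule names the 10 highest and 10 lowest called genes with 1 sign in all phases. For a single phase it names 5 and 5 whose extracts do not overlap between strains. For growth in the parent it names 10 and 10 whose extracts do not overlap between the 2 phases. The other contrasts have 5 and 5, and each described list its 4 largest called members. For growth in the deletion strain and at comparable density the named genes were also held to extracts without overlap, which the preset rule did not ask. Unnamed features were passed over for a count, with at most 2 each way. arcA, arcC, sucD and glyA, called in the average without 1 sign in all phases, are named as list members, and genes that did not pass are named as values only, chosen after they were seen. The lists were tested with limma's camera among the 133 named genes (preset correlation 0.01, then estimated) and with fry: 19 lists had a named member, 12 had at least 3 and were tested. glmS, tRNA ligases caught by the amino acid pattern and pyrF were taken out of lists where the symbol pattern misplaced them, after the symbols were seen. List names are wider than their named members. The archaella and chemotaxis list holds che and htr genes and no archaellum gene. The bacteriorhodopsin, retinal and carotenoid list holds bat, hop, sop1 and sop2 and no gene of a retinal or carotenoid synthesis enzyme.

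Alternatives covered background correction, normalization, removal of the dimmest 25% of features, the deposited table, replicate number and slide series as blocks, single dye orientations, all 42 arrays with the extract as a random block, only the groups compared in the fit (for the average, only mid and late log), other phases or optical density in the contrast, a minimum absolute log2 change of 1, and leaving out each extract. Slide series were read from the largest gap in the slide numbers (11 extracts in the first, 10 in the second). A smaller gap within the first parts the extracts numbered 1 from the log phase extracts numbered 2. The series block does not take out a difference between those runs. Fits within a series, with 5 and 2 residual degrees of freedom, are given on their own and are not counted where a number of alternatives is given. The 2 treatments of the doubted array, the list tests under them, with the replicate block and without csg, gatC and htr18, the fits within a slide series and, for called genes outside the naming rule, the fits without 1 extract were added after seeing the data. Figures were drawn with matplotlib 3.10.9.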

Results

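Transcript levels of the halophilic archaeon Halobacterium salinarum NRC-1 were measured along the growth curve of a strain that lacks the gene VNG1451C and of a ura3 strain, called the parent here. Cultures grew in peptone-rich complex medium with shaking in light and were sampled in 4 phases, from early log through mid and late log to stationary. The series holds 42 arrays of 21 RNA extracts, each extract hybridised as a pair with exchanged dyes against RNA of mid log wild type. The parent has 2 extracts in early log, 3 in mid log, 3 in late log and 2 in stationary phase, and the deletion strain has 3, 3, 3 and 2. The series design calls them biological replicates. The 2 or 3 extracts per group limit the precision, since the paired arrays of an extract repeat the same RNA.

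The deletion cultures were less dense than the parent in every phase. The mean OD600 in early log was 0.153 ± 0.0321 (SD, n = 3) in the deletion strain and 0.321 ± 0.0177 (SD, n = 2) in the parent. In mid log it was 0.273 ± 0.0849 (SD, n = 3) and 0.524 ± 0.0259 (SD, n = 3), and in late log 0.344 ± 0.0652 (SD, n = 3) and 0.777 ± 0.0473 (SD, n = 3). In stationary phase it was 0.605 ± 0.0636 (SD, n = 2) and 1.22 ± 0.0566 (SD, n = 2). A strain comparison within a phase is therefore also a comparison between densities.

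pyrF, the gene behind the ura3 label, encodes orotidine 5'-phosphate decarboxylase of pyrimidine synthesis. It lay below the wild type reference in 21 of 21 extracts and on 42 of 42 arrays, with a mean log2 ratio of -1.14 ± 0.36 (SD, n = 21) and a range from -1.92 to -0.52. pyrF exceeded background on 23 of 42 arrays, so the size of this ratio is uncertain, and in the deposited value table it was -0.0823. VNG1451C is not among the probes named here and its level was not analysed here, so the deletion had no check by its own probe.

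Averaged over the 4 phases, genes of NAD synthesis had the highest and ppsA the lowest value in the deletion strain against the parent among the named genes past the test. nadC (quinolinate phosphoribosyltransferase) rose by 2.43 ± 0.18 log2 units (SE), with an adjusted p of 1.20e-07 (limma). nadA (quinolinate synthase) rose by 1.27 ± 0.16 (SE; adjusted p = 6.65e-05), and ppsA (phosphoenolpyruvate synthase, a gluconeogenic enzyme) fell by 0.93 ± 0.09 (SE; adjusted p = 1.59e-06). cobN, a gene of cobalamin synthesis, rose by 0.43 ± 0.09 (SE; adjusted p = 0.00736). glnA (glutamine synthetase) fell by 0.54 ± 0.11, serB (phosphoserine phosphatase) fell by 0.48 ± 0.12 and pyrB (aspartate transcarbamoylase) fell by 0.24 ± 0.06 (SE), with adjusted p of 0.00878, 0.0269 and 0.0244. Each of these 7 differences had 1 sign in all 4 phases as labelled. In stationary phase, however, ppsA stood at only -0.19 ± 0.19 (SE; adjusted p = 0.552), at -0.58 without an array of unsettled dye direction (0.0598) and at -0.26 with its sign turned (0.403), and pyrB at -0.06, or 0.04 with that sign turned. The test of whether the ppsA difference itself changed from early log to stationary phase did not pass (0.75 ± 0.26, SE; adjusted p = 0.206). Of the single phases serB passed only in stationary phase, at -1.23 log2 units. nadC exceeded background on 33 and nadA on 35 of 42 arrays, so the size of their changes is uncertain here and in each phase.

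Of 2688 features, 116 differed in this average, 54 higher and 62 lower in the deletion strain, among them 11 of the 133 named genes. Of unnamed features, spot3717 rose by 3.16 ± 0.20 and spot3081 by 1.93 ± 0.20, while spot787 fell by 1.11 ± 0.13 and spot4845 fell by 1.02 ± 0.16 log2 units (SE). Leaving out the array of unsettled dye direction gave 156 features, 102 of them shared, and turning its sign 136, 88 of them shared, and the 7 genes above passed in both. Without 1 extract the count was 63 (parent early log 2), 73 (parent early log 3), 77 (deletion early log 2), 75 (deletion mid log 2), 70 and 72 (parent late log 2 and 3), 65 (deletion late log 3), 60 (parent stationary 3) and 185 (deletion stationary 2). nadC, nadA, ppsA, glnA and cobN passed without any single extract. serB did not pass without parent early log 2 or 3, mid log 2, late log 2 or 3 or stationary 3, or deletion late log 3 (adjusted p from 0.0503 to 0.0989). pyrB did not pass without parent early log 3 or late log 2, deletion late log 3 or deletion stationary 3 (0.0507 to 0.0871). Over 37 alternatives nadC passed in all (adjusted p from 1.72e-12 to 2.11e-04), and the adjusted p of ppsA ran from 6.11e-10 to 0.0536 (35 passed) and that of nadA from 1.13e-07 to 0.144 (35 passed). cobN and glnA passed in 31 each, pyrB in 27 and serB in 23. With slide series as a block 112 features passed, with nadC at 2.42 and ppsA at -0.93; the first series holds no stationary extract. The second has 1 extract per strain in each log phase and 2 residual degrees of freedom, so calls missed there say nothing about stability; in it alone 3 features passed, with nadC at 2.50 (adjusted p = 0.00620) and ppsA at -0.86 (adjusted p = 0.336).

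Both named genes of arginine fermentation rose in this average, arcC (carbamate kinase) by 0.69 ± 0.17 and arcA (arginine deiminase) by 0.44 ± 0.11 (SE; adjusted p = 0.0291 and 0.0367), with stationary estimates of -0.80 and -0.72 that did not pass. Of the 21 fits without 1 extract arcA passed in 11 and arcC in 13. Neither passed without parent early log 2, deletion early log 2 or 3, mid log 2 or late log 3, parent stationary 2 or deletion stationary 2. arcA also failed without parent mid log 1 or deletion mid log 1 or late log 1 and arcC without parent early log 3 (adjusted p up to 0.0979 and 0.0696). In the citric acid cycle list sucD (succinyl-CoA synthetase) rose by 0.40 ± 0.09 (SE) and 5 of 6 members did not pass. Of the single phases sucD passed only in stationary phase, which holds the doubted array. It stood there at 1.17 as labelled, 0.80 with that array left out and 0.71 with it turned. In the amino acid synthesis list glnA and serB fell and glyA (glycine hydroxymethyltransferase) rose by 0.40 ± 0.10 (SE), while 12 of 15 did not pass; glyA did not pass with the sign of the doubted array turned (0.26, adjusted p = 0.121). sucD passed in 21 of 21 fits without 1 extract and glyA in 9. The extracts without which glyA failed were parent early log 2 and 3, mid log 1, late log 1 and 3 and stationary 3, and deletion early log 2 and 3, mid log 2 and 3, late log 3 and stationary 3 (adjusted p from 0.0504 to 0.0915). In gluconeogenesis and glycolysis ppsA fell, and eno (0.01 ± 0.10) and tpiA (0.18 ± 0.09, SE) did not pass; the median of the 3 was 0.01, while the mean (-0.25) and camera's direction were below 0. Of 4 pyrimidine synthesis genes pyrB fell, and of 4 cobalamin synthesis genes cobN rose.

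No member passed in purine synthesis (7 genes), thiamine synthesis (3), bacteriorhodopsin, retinal and carotenoid synthesis (4), archaella and chemotaxis (11), ribosomal proteins (2), translation factors and tRNA ligases (13), chaperones and proteasome (6) or DNA replication and repair (7). Median and mean differed in sign for chaperones and proteasome (-0.05 and 0.03) and DNA replication and repair (-0.01 and 0.01), with camera's direction downward, and for purine synthesis (-4.06e-04 and 0.05), with it upward. Lists with 1 named gene stood at 0.15 (nuoL, respiratory chain), -0.08 (glpK, glycerol), -0.09 (msrA, oxidative stress), -0.30 (dpsA, iron) and -0.37 (phoU, phosphate uptake), none past the threshold over all genes. nuoL and phoU had an unadjusted p under 0.05 (limma), since adjusting over a list of 1 gene changes nothing. phoU passed with the doubted array left out (-0.54, adjusted p = 0.00116) and turned (-0.60, adjusted p = 0.00129). No list passed camera in the average (lowest adjusted p = 0.322), with pyrimidine synthesis at an unadjusted p of 0.0376.

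**Figure D1:**
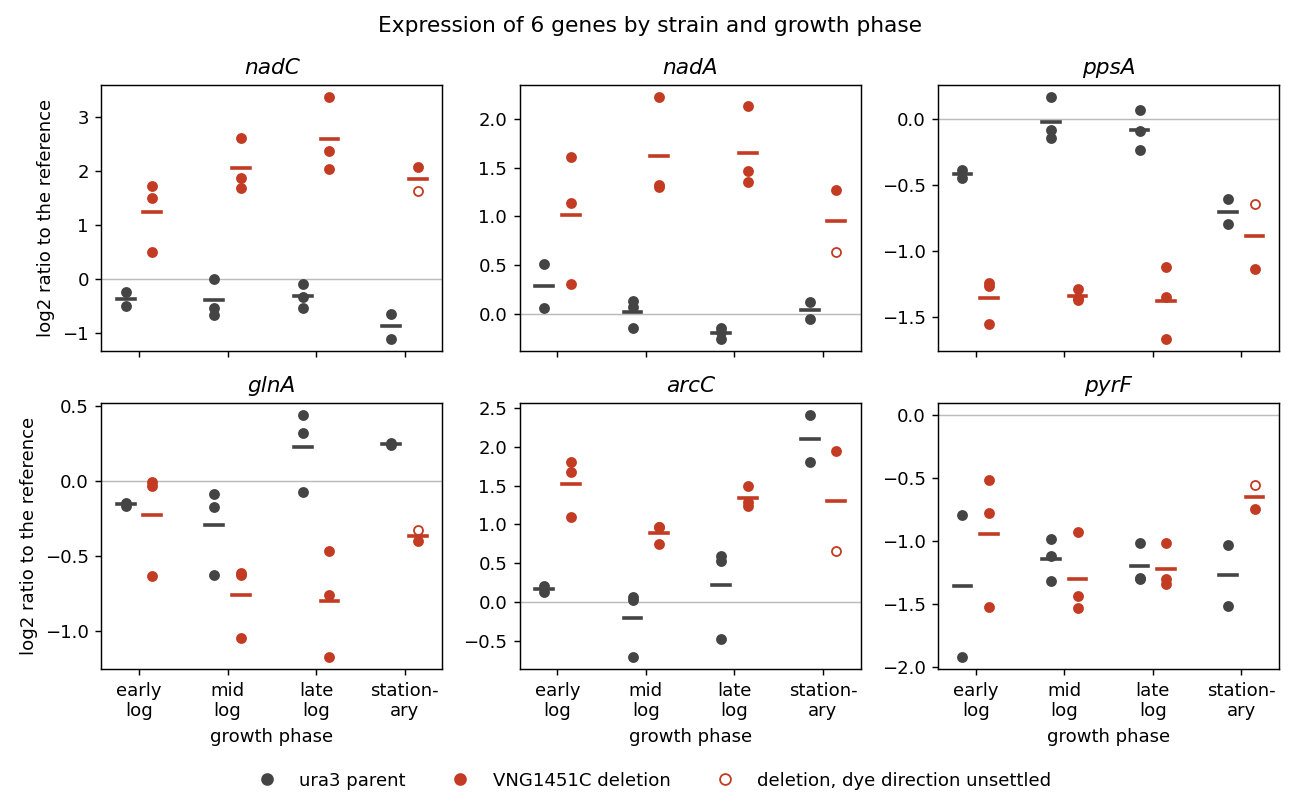
Log2 ratio to the wild type reference (vertical axis) by growth phase (horizontal axis) for 6 genes, with 1 point per RNA extract and bars at the group means; the open point is the deletion extract with an array of unsettled dye direction. Averaged over phases nadC and nadA lie higher in the deletion strain by 2.43 and 1.27, ppsA stands at -0.93 against the parent, and pyrF lies below 0 in 21 of 21 extracts.

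In early log phase ppsA was the only named gene past the test, at -1.36 ± 0.17 (SD, n = 3) in the deletion strain and -0.42 ± 0.04 (SD, n = 2) in the parent. ppsA fell by 0.94 ± 0.18 log2 units (SE; adjusted p = 0.0252). nadC had an estimate of 1.61 ± 0.37 (SE) that did not pass (adjusted p = 0.115). In all, 7 features passed, 2 higher and 5 lower. The count was 0 without parent replicate 2 (limma; 56 at an unadjusted p under 0.05), 3 without parent replicate 3, 12 without deletion replicate 1 and 2 without deletion replicate 2 or 3, and ppsA passed in none of these 5 fits (adjusted p from 0.0646 to 0.394). Within the first slide series, which has 1 parent extract here, ppsA stood at -0.96 and within the second, 1 extract against 1, at -0.86. With the series as a block ppsA stood at -0.93 (limma, adjusted p = 0.0348) and 7 features passed. Over 20 alternatives the adjusted p of ppsA ran from 0.00530 to 0.967 and 8 passed.

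In mid log phase nadC rose by 2.45 ± 0.34 (SE; adjusted p = 5.54e-04), from -0.39 ± 0.35 (SD, n = 3) in the parent to 2.06 ± 0.48 (SD, n = 3) in the deletion strain. nadA rose by 1.59 ± 0.29 (SE; adjusted p = 0.0145) and ppsA fell by 1.32 ± 0.16 (SE; adjusted p = 1.77e-04). For these 3 genes all 3 deletion extracts lay on 1 side of all 3 parent extracts. In all, 9 features passed, 6 higher and 3 lower. Among 4 pyrimidine synthesis genes none passed over all genes and 2 passed adjusted over the list alone, and the list lay lower by camera (adjusted p = 0.0208), with adjusted p = 0.253 with an estimated correlation. Gluconeogenesis and glycolysis lay lower too (adjusted p = 0.0436; adjusted p = 0.253 with an estimated correlation), with ppsA its only called member. With the replicate number as a block this list did not pass camera (adjusted p = 0.129). Pyrimidine synthesis then passed (1.57e-04, or 0.0689 with an estimated correlation), as did purine synthesis, upward (0.0286, or 0.419). The count was 5 without parent replicate 3 and 4 without deletion replicate 1, and 16 with the doubted stationary array, which enters only the shared spread, left out. nadA did not pass without parent 1, 2 or 3 (adjusted p = 0.0511, 0.0657 and 0.0913) or deletion 1 (0.137). Within slide series, the second with 1 extract against 1, nadC stood at 2.48 and 2.41 and ppsA at -1.40 and -1.14, with 0 features passing in either (limma; 159 and 11 unadjusted); with the series as a block 12 passed, nadC at 2.45 and nadA at 1.59 among them. Over 21 alternatives nadC and ppsA passed in 19 each and nadA in 14, with the adjusted p of nadA from 4.78e-04 to 0.857.

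In late log phase the NAD genes again stood highest among named genes, with nadC risen by 2.91 ± 0.34 (SE; adjusted p = 8.33e-05) and nadA by 1.85 ± 0.29 (SE; adjusted p = 0.00173). ppsA fell by 1.29 ± 0.16 (SE; adjusted p = 1.13e-04). phoU, a regulator of phosphate uptake, fell by 1.29 ± 0.24 (SE; adjusted p = 0.00552), from 1.15 ± 0.23 (SD, n = 3) in the parent to -0.14 ± 0.12 (SD, n = 3). glnA fell by 1.03 ± 0.21 (SE; adjusted p = 0.0117). In all, 33 features passed, 5 higher and 28 lower. Without parent replicate 2 the count was 19, and neither phoU (adjusted p = 0.0519) nor glnA (0.0966) passed; glnA also failed without parent 3 (0.0670) or deletion 1 (0.0993). Within slide series, the second with 1 extract against 1, nadC stood at 2.92 and 2.90 and ppsA at -1.31 and -1.26, with 3 features, phoU among them (-1.38), and 0 features passing (limma; 122 and 52 unadjusted). With the series as a block 34 passed. Over 21 alternatives the adjusted p of phoU ran from 1.62e-04 to 0.769 (16 passed); glnA passed in 15, nadC and ppsA in 20 each and nadA in 19.

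In stationary phase the direction of 1 array is unsettled. The exchanged arrays of deletion replicate 3 correlated at -0.446 over all features, where the other 3 stationary pairs had 0.699 to 0.834. The array labelled as its flip correlated at -0.449 to -0.179 with the other 7 stationary arrays, which correlated among themselves at 0.537 to 0.871, both without the dimmest 25% of features. The labels state its dyes, so it was kept as labelled, and the counts, the gene lists and the named genes that use it were fitted again with the array left out and with its sign turned, both chosen after seeing the data.

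With the dyes as labelled nadC rose by 2.73 ± 0.41 (SE; adjusted p = 7.94e-04), and it also passed with the array left out (3.25) and turned (2.43). sucD rose by 1.17 (0.80 and 0.71 in those versions), gdhA1, a glutamate dehydrogenase gene, by 1.22 (0.97 and 1.09), serB fell by 1.23 (-1.29 and -1.33) and bat, the activator gene of bacteriorhodopsin synthesis, above background on 33 of 42 arrays, fell by 0.86 (-0.78 and -0.76); these 4 passed in all 3 versions. nadA (0.92, adjusted p = 0.131) and ppsA (-0.19) did not pass, nadA passing with the array left out (1.36, adjusted p = 0.0242). The ribosomal protein genes rpmC and rpl12p rose by 1.30 and 1.20 as labelled and stood at 0.88 and 0.91 with the array left out (adjusted p = 0.103 and 0.0648), while turned they passed at 1.05 and 1.10 (0.0460 and 0.0325). As labelled 138 features passed, 79 higher and 59 lower, against 180 with the array left out (90 shared) and 233 with its sign turned (78 shared). The count was 284 without parent 2, 21 without parent 3, 502 without deletion 2 and 30 without deletion 3. Without parent 3 none of rpmC, rpl12p, gdhA1, sucD, serB and bat passed (adjusted p from 0.0531 to 0.331). Without deletion 3 only nadC and sucD of these passed (serB, the lowest of the rest, at 0.0803), and without parent 2 rpl12p (0.0663) and bat (0.0508) did not. All 4 stationary extracts lie in the second slide series, and fitted alone, with 2 residual degrees of freedom, they gave 8 features, with nadC (adjusted p = 0.0246) and none of the other named genes given here. Over 19 alternatives nadC passed in 16 (adjusted p at most 0.156), sucD in 15, serB in 13, rpmC and gdhA1 in 11 each, rpl12p in 9 and bat in 7.

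With the dyes as labelled 3 lists passed camera in stationary phase, and with the array left out none did (limma's camera; 1 of 12 lists unadjusted, 2 by fry; adjusted p from 0.301 to 0.383 for these 3). The citric acid cycle list lay higher as labelled (adjusted p = 0.0387; adjusted p = 0.430 with an estimated correlation), with sucD and sucC risen among 6, and had an adjusted p of 0.1996 with the array turned. sucC rose by 0.81 as labelled and stood at 0.35 with the array left out (adjusted p = 0.237) and 0.38 turned (0.178), and sucC did not pass without parent 3 (0.284) or deletion 3 (0.355). The bacteriorhodopsin, retinal and carotenoid list, without a named gene of a synthesis enzyme, lay lower as labelled (adjusted p = 0.0372; adjusted p = 0.140 with an estimated correlation). In it bat had fallen among 4, and it had 0.225 with the array turned. Archaella and chemotaxis lay lower as labelled (adjusted p = 0.0387; adjusted p = 0.430 with an estimated correlation) with none of 11 past the threshold, and passed with the array turned (0.00916; adjusted p = 0.495 with an estimated correlation). Without csg, gatC and htr18, for which no value is given, archaella and chemotaxis had an adjusted p of 0.109 and the citric acid cycle list 0.0505, with the dyes as labelled.

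To bring the densities closer, deletion mid log was compared with parent early log. nadC rose by 2.43 ± 0.37 (SE; adjusted p = 0.00370) and ppsA fell by 0.92 ± 0.18 (SE; adjusted p = 0.0256). nadA had an estimate of 1.33 ± 0.33 (SE) that did not pass (adjusted p = 0.111). In all, 7 features passed, 4 higher and 3 lower. The count was 2 and 4 without parent replicate 2 or 3 and 4 without deletion replicate 1, and through the shared spread 11 and 13 with the doubted stationary array left out or turned. ppsA passed in none of the 5 fits without 1 extract (adjusted p from 0.0553 to 0.248), and nadC did not pass without parent replicate 2 (2.30, adjusted p = 0.119). With slide series as a block 11 features passed. Within the first series, with 1 parent extract, nadC stood at 2.65, and within the second, with 1 extract against 1, at 2.12. Over 21 alternatives nadC passed in 18 and ppsA in 9 (adjusted p from 0.00316 to 0.724). The share that was higher was 57.1%, and 80.0% of 5 under median centring.

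In the parent, transcripts of the ribosomal protein genes rpl12p and rpmC and the glutamate dehydrogenase genes gdhA1 and gdhA2 were lower in stationary phase than in early log. Those of the arginine fermentation genes arcC and arcA and of 9 of 11 taxis genes were higher. The ribosomal protein and arginine fermentation lists were too short to be tested. rpl12p fell by 2.64 ± 0.32 and rpmC fell by 2.27 ± 0.33, both members of the ribosomal protein list, and gdhA1 fell by 2.18 ± 0.27 and gdhA2 fell by 1.69 ± 0.30 (SE). gdhB, another glutamate dehydrogenase gene, named after its value was seen, rose by 0.59 ± 0.21 (SE; adjusted p = 0.0404) and passed in 0 of 4 fits without 1 extract (limma; adjusted p from 0.0709 to 0.194). arcC rose by 1.94 ± 0.39, arcA by 1.75 ± 0.25, serB by 1.42 ± 0.26 and dpsA, a DNA-protecting ferritin-like protein, by 1.13 ± 0.35 (SE). Of 11 archaella and chemotaxis genes 9 rose and none fell, with htr7 at 1.25, htr6 at 1.08, cheR at 1.08 and htr1 at 1.02, and all 9 passed adjusted over the list alone. htr18, not above background in at least 1 group, is among the 9 and enters the list tests. The list rose by camera (adjusted p = 6.82e-07; adjusted p = 0.0550 with an estimated correlation), and without csg, gatC and htr18 8 of 10 rose (adjusted p = 2.13e-06; adjusted p = 0.0640 with an estimated correlation). In the bacteriorhodopsin, retinal and carotenoid list bat and sop1 rose (camera adjusted p = 0.125).

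Further genes past the threshold in the parent were hisF of histidine synthesis (-1.29), the enolase gene eno (-1.27), the mevalonate kinase gene mvk (-1.19, and 0.23 in the deposited value table), secY of the protein translocase (-1.16), sucD (-1.12), cmk (-1.09), msrA (1.08) and bat (1.05). In the citric acid cycle list 4 of 6 fell, sucD, sucC, icd and citZ (camera adjusted p = 0.125). Of 13 translation factor and tRNA ligase genes 4 fell, cysS, proS, aspS and ileS (camera adjusted p = 0.246). Without early log 2 cysS (adjusted p = 0.208) and citZ (0.0603) did not pass, and without early log 3 citZ (0.149), aspS (0.0787) and ileS (0.305) did not. Without stationary 2 cysS (0.151) and citZ (0.179) did not pass, and without stationary 3 cysS (0.0732), aspS (0.0923), ileS (0.295) and proS (0.0787) did not. In all, 783 features passed, 375 higher and 408 lower, including 46 named genes. The share that was higher was 47.9%, and 33.2% of 515 under median centring. Without early log replicate 2 the count was 417 and without stationary replicate 3 it was 345, and dpsA did not pass without either (adjusted p = 0.0792 and 0.156) or without early log replicate 3 (0.0808). With slide series as a block 697 passed, and in the second series alone 0 (limma; 439 unadjusted), with rpl12p at -2.53 (adjusted p = 0.0638) and arcA at 1.61. Over 20 alternatives rpl12p and arcA passed in all and dpsA in 14 (adjusted p from 0.00136 to 0.156).

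In the deletion strain the same comparison uses the array of unsettled direction. cheA rose by 1.09, cheR by 1.01, cheY by 1.01 and htr6 by 0.89, and these 4 taxis genes passed in all 3 versions. With the array left out they stood at 1.12, 1.18, 1.11 and 0.84, and with its sign turned at 0.62, 0.68, 0.69 and 0.69, and htr6 was -0.11 in the deposited value table. rpl12p fell by 1.28, gdhA2 fell by 1.24, rpmC fell by 0.97, secY fell by 0.74 and cmk fell by 0.66, again in all 3 versions. uvrB, a DNA repair gene, rose by 0.91 as labelled and by 0.73 with the array left out, and stood at 0.32 (adjusted p = 0.321) with the sign turned. Of 11 archaella and chemotaxis genes 7 rose and none fell (camera adjusted p = 9.24e-07; adjusted p = 0.0592 with an estimated correlation), and 8 passed adjusted over the list alone. With the array left out 9 rose (camera adjusted p = 1.74e-05; adjusted p = 0.109 with an estimated correlation) and with its sign turned 6 (camera adjusted p = 3.55e-04; adjusted p = 0.257 with an estimated correlation), htr7 (0.46, adjusted p = 0.246) and htr8 (0.43, adjusted p = 0.0598) not among them. Of 13 translation factor and tRNA ligase genes 1 fell as labelled (camera adjusted p = 0.545), 7 with the array left out (0.0128; adjusted p = 0.365 with an estimated correlation) and 8 with it turned (0.00157; adjusted p = 0.257 with an estimated correlation). htr7 passed in 1 and htr8 in 2 of the 5 fits without 1 extract, failing without early log 1 (adjusted p = 0.156 and 0.0759) and stationary 2 (0.118 and 0.142), htr7 also without early log 2 (0.0570) and stationary 3 (0.106) and htr8 without early log 3 (0.0663).

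As labelled 324 features passed in the deletion strain, 217 higher and 107 lower (67.0% higher, and 91.7% of 48 under median centring). With the array left out 696 passed, 291 of them shared, and with its sign turned 596, 207 of them shared. Without early log replicate 1 the count was 182, and rpmC, secY and cmk did not pass (adjusted p = 0.171, 0.114 and 0.0532). Without stationary replicate 2 rpl12p, gdhA2, rpmC, secY and cmk did not pass (0.0539 to 0.232), and without stationary replicate 3 uvrB did not (0.0674). With slide series as a block 217 passed and rpmC did not (-0.93, adjusted p = 0.0922), and in the second series alone 0 features passed (limma; 189 unadjusted), with cheA at 1.01. Over 21 alternatives cheA passed in 19 (adjusted p from 2.40e-08 to 0.287), uvrB in 13 (4.13e-05 to 0.946) and rpmC in 10 (0.00184 to 0.375).

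**Figure D2:**
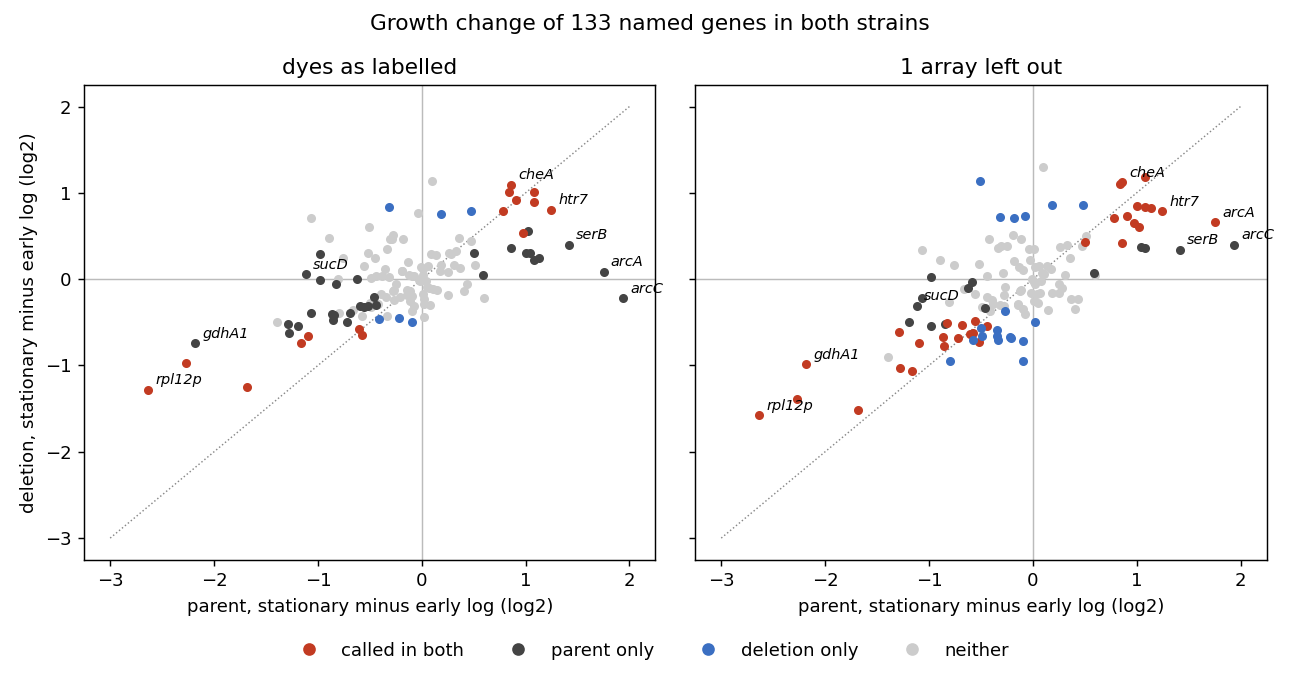
Stationary minus early log change in log2 units of each of the 133 named genes in the parent (horizontal axis) and in the deletion strain (vertical axis), with the dyes as labelled (left) and with the doubted array left out of the deletion's change (right); colours give the test at an adjusted p of 0.05, with the parent's test as labelled in both panels, and the dotted line marks equal change. arcA and arcC rose in the parent by 1.75 and 1.94 and lie below the dotted line in both panels.

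The growth change itself differed between the strains for 25 features, 13 with a higher and 12 with a lower change in the deletion strain. arcA rose by 1.75 in the parent and had 0.09 ± 0.23 (SE) in the deletion strain, a difference of -1.67 ± 0.34 (SE; adjusted p = 0.0242). arcC had a difference of -2.16 ± 0.52 (SE) that did not pass (adjusted p = 0.0546), nor with the array left out (-1.54, adjusted p = 0.0743), but passed turned (-1.86, adjusted p = 0.0346). sucD had -1.12 in the parent and 0.06 in the deletion strain, a difference of 1.18 ± 0.27 (SE; adjusted p = 0.0382). With the doubted array left out 49 features passed, 22 of them shared, and arcA did not (-1.09, adjusted p = 0.117), while arcA rose in the deletion strain by 0.66 (adjusted p = 0.0414); with its sign turned 82 passed, 21 of them shared, arcA among those past the test (-1.32, adjusted p = 0.0327), and sucD did not (0.73, adjusted p = 0.0578). The count was 8 and 16 without parent early log 2 or 3, 65, 13 and 13 without deletion early log 1, 2 or 3, 83 and 7 without parent stationary 2 or 3, and 154 and 6 without deletion stationary 2 or 3. sucD did not pass without parent early log 2 or 3, deletion early log 2 or 3, parent stationary 3 or deletion stationary 3 (adjusted p from 0.0715 to 0.265), and arcA failed without the same extracts except parent early log 3 (0.0609 to 0.199). With slide series as a block 27 features passed, with sucD at 1.18 and arcA at -1.70, and in the second series alone 0 (limma; 103 unadjusted), with sucD at 1.15. Over 25 alternatives sucD passed in 10 (adjusted p from 0.00115 to 0.440) and arcA in 12 (0.00560 to 0.295). The share of features with a higher change was 52.0%, and 80.0% of 5 under median centring.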

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

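The tests of the doubted array and of optical density were chosen only after the result was seen, and the fits within slide series were added after seeing the data. The 25 features whose stationary against early log change differed between the strains stand out because the difference itself passed a test. Among named genes these are sucD with a difference of 1.18 and arcA with -1.67 log2 units.

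Those differences rest on the deletion stationary group, in which the dye pair of replicate 3 runs opposite. Dye bias of dim spots would leave the brighter features in agreement, and there the pair correlated at -0.406, which argues against it. A wrong dye label stays open. Turning the array makes its correlations with the 6 stationary arrays of other extracts positive by construction. These correlations then reached only 0.449, below the 0.537 to 0.871 among the other 7 arrays. As labelled, pyrF lay below the reference on this array too, as on 42 of 42 arrays, a sign that turning would reverse. That is 1 gene, above background on 23 of 42 arrays, so it does not settle the label. Another fault of that array was not tested. Both arrays are said to hold the same extract, so no biological explanation was tested.

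Over the 11 named genes called in the averaged strain contrast the median ratio to the averaged change was 0.987 at comparable density (quartiles 0.803 and 1.05) and 1.07 with optical density as a covariate (quartiles 1.02 and 1.31). For these genes as a set that argues against lower density as the whole source, although they were chosen by the average, the contrasts share extracts, and singly only nadC (not without parent early log 2) and ppsA (in 0 of 5 fits without 1 extract) passed at comparable density. Density stays open for serB and sucD, whose ratios were 0.608 and 0.912 at comparable density but 0.141 and 0.292 with the covariate. Taken singly, it also stays open for glnA, pyrB and glyA. These did not pass at comparable density (limma, adjusted p = 0.445, 0.811 and 0.811). With the covariate they did not pass either (0.0769, 0.0777 and 0.0700), at ratios of 1.01, 1.39 and 1.23. Density stays open too for features outside these 11: in all 199 passed with the covariate, 41 of them shared with the 116. Within the slide series the smaller median ratio was 0.973, but this decides nothing, since both strains are spread over the series nearly alike (a series shift enters the average with a weight of -0.0417) and the genes were chosen by that average. An effect of the deletion itself and other differences between the cultures were not tested and stay open.

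In mid log the real split of the 6 extracts gave 9 calls and the highest of the other splits 0, so 1 of 10 splits was as large. In late log the real split gave 33 and the highest other 0, again 1 of 10. With 10 splits the share cannot fall under 0.05. For the averaged contrast 1 of 100 splits within phases, the real one, reached 116 calls, and the highest other gave 52. Among the splits drawn, that argues against chance as the source of the count as a whole. It does not exclude chance and does not tell which of the 116 features differ. In the other splits a real strain difference would add to the spread and hold their counts down.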

How the results depend on the processing

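Fits within a slide series, the 2 treatments of the doubted array and lists without csg, gatC and htr18 or with the replicate block were chosen after seeing the data. Outside the fits within a slide series 1023 of 1282 values of named genes kept their direction and call, 257 kept the direction without passing and 2 reversed, both in the deposited value table: mvk in the parent's growth at 0.23 and htr6 in the deletion's growth at -0.11. For these and the counts that follow, the cause was not tested unless stated. Aquantile scaling, counted among the alternatives, leaves the ratios as they are and tests nothing. The 2 treatments of the doubted array leave the estimates of comparisons without deletion stationary phase unchanged. Of 57 values, 8 kept direction and call in the deposited table, 26 with plain subtraction, 35 with median centring and 36 on flipped arrays. This count was 49 without background correction, 49 on arrays with the sample in Alexa 547 and 57 without dim features. Removal of dim features and, for the average, a fit of only mid and late log (84 calls) moved no count by over 1.5 times; the first put the median of all features at 0.12 in stationary phase and 0.14 in the growth difference. Signal over background limits the ratios of pyrF, nadC and nadA, above background on 23, 33 and 35 of 42 arrays. Plain subtraction, which drops values under 0, left fewer calls in each of the 9 comparisons, with a median of all features of 0.11 in the growth difference. ppsA in early log (-0.98) and rpl12p in stationary phase (1.41), above background on 42 of 42 arrays, were among the calls lost.

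Counts of features follow in the order early log, mid log, late log, stationary, average, parent growth, deletion growth, growth difference and comparable density, with only those that moved by over 1.5 times. The deposited table, whose scale and centring are unknown, gave 0, 0, 2, 8, 8, 70, 4, 1 and 0 (limma; 52, 38 and 32 unadjusted for the counts of 0), with medians of all features at -0.72 to 0.25, and the ratio of pyrF, the deleted gene, stood at -0.0823. Plain subtraction gave 0 in early log (119 unadjusted), 3 in mid log, 3 in late log, 3 in stationary phase, 20 in the average, 359 and 78 for growth and 1 for the growth difference. Without background correction stationary phase gave 70 and the growth difference 16. Median centring gave 18 in late log, 39 in stationary phase, 38 in the average, 515 and 48 for growth and 5 for the growth difference. Arrays with the sample in Alexa 547 gave 2 in early log, 59 in stationary phase, 547 for deletion growth and 8 for the growth difference. Flipped arrays gave 0 in early log (50 unadjusted), 1 in mid log, 18 in late log, 34 in the average, 371 and 82 for growth, 1 for the growth difference and 1 at comparable density. All 42 arrays with a random block gave 23, 67, 286 and 199 from mid log to the average, 111 for the growth difference and 28 at comparable density. The correlation between dye partners in that fit was only 0.170. It thus weighs the 2 arrays of 1 RNA nearly as separate samples, and its larger counts are no firmer.

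Fitting only the groups compared, with fewer samples behind the spread, gave 1 in early log, 8 in stationary phase, 517 and 0 (455 unadjusted) for growth and 2 for the growth difference. Asking for a log2 change of 1 left 66 in stationary phase, 7 in the average and 309 and 75 for growth. Optical density as a covariate gave 199 in the average, 41 of them shared. Stationary minus mid log gave 87 in the deletion strain, and deletion stationary minus parent mid log 219. Slide series as a block gave 11 at comparable density. The first series holds 1 parent early log extract, so no count within it is given for early log or comparable density. Within the first series the counts were 0 in mid log (159 unadjusted) and 3 in late log. Within the second, which has 1 extract per strain in each log phase and 2 residual degrees of freedom, so that a missed call says nothing about stability, they were 0 in early, mid and late log (24, 11 and 52 unadjusted), 8 in stationary phase, 3 in the average, and 0 for both growth comparisons, their difference and comparable density (439, 189, 103 and 15). Leaving out the doubted array gave 16 in mid log, 696 for deletion growth, 49 for the growth difference and 11 at comparable density. Turning it gave 233 in stationary phase, 596 and 82 for the same growth results and 13 at comparable density.

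Leaving out 1 extract gave 0 to 12 in early log, 4 to 12 in mid log, 19 to 41 in late log, 21 to 502 in stationary phase, 60 to 185 in the average, 345 to 732 and 182 to 305 for growth in parent and deletion, 6 to 154 for the growth difference and 2 to 8 at comparable density. A lone extract left in a group is assumed to vary like the other groups.

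Titles number only replicates 2 and 3, which leaves 2 numbered pairs in each comparison of a pair of groups. For that reason the numbers were not taken to pair the samples, a choice made when the counts with the block were known. Extracts of 1 number deviated together in 43 of 66 pairs (correlation over 0.1, median 0.192, range -0.277 to 0.669), which does not speak against pairing. The stationary strain pairs stood at -0.277. With 2 extracts in each group these 2 pairs are a single value by construction, and it includes the extract with the doubted array. It therefore decides nothing about pairing. As hints from the data, 18 of 21 extracts correlated best with their own number. With unnumbered extracts counted as 1, all 3 strain pairs deviated together in mid log (0.204 to 0.430) and in late log (0.211 to 0.315). In these phases replicate 3 is also the second slide series, and replicates 1 and 2 are separate runs of slide numbers within the first. Pairing and an effect of the slide run cannot be told apart there. With the replicate block the counts were 25, 24, 52, 312 and 175 from early log to the average, 123 for the growth difference and 17 at comparable density. In mid log 2 lists passed camera with it, pyrimidine synthesis (adjusted p = 1.57e-04; adjusted p = 0.0689 with an estimated correlation) and purine synthesis, upward (0.0286; adjusted p = 0.419 with an estimated correlation), while gluconeogenesis and glycolysis had 0.129, and in late log 0 passed (limma's camera; lowest adjusted p = 0.430).

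Lists past camera fell to 0 with an estimated correlation in mid log, in stationary phase and in both growth comparisons. Of 3 in stationary phase 0 passed with the doubted array left out, 1 with it turned and 1 without csg, gatC and htr18, and deletion growth had 2 in place of 1 with it left out or turned. With fry, which tests whether members move one way, 0 lists passed in early log and at comparable density, 3 passed in mid log, 1 in late log, 4 in stationary phase, 2 in the average, 7 in parent growth, 2 in deletion growth and 1 for the growth difference. In the average 9 list members were called and at comparable density 1.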

Other observations

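The versions with the doubted array left out or turned and the fits of these genes without 1 extract were chosen only after the result was seen. Of 3 thiamine synthesis genes thiC and thiD rose from early log to stationary phase in the deletion strain by 0.78 ± 0.23 and 0.75 ± 0.22 log2 units (SE; adjusted p = 0.0346 and 0.0315), by 0.86 and 0.86 with the doubted array left out and by 0.90 and 0.97 with it turned. The third, thiL, had -0.43 (adjusted p = 0.181), and fell by 0.71 with the array left out and by 0.74 with it turned (adjusted p = 0.00512 and 0.00573), and the list did not pass camera (adjusted p = 0.545). Neither thiC nor thiD passed without early log 1 (adjusted p = 0.127 and 0.127) or stationary 2 (0.141 and 0.167), and thiC did not without stationary 3 (0.0671). In the parent thiC and thiD had 0.48 and 0.19 and did not pass, and the difference between the strains did not pass for either (adjusted p = 0.650 and 0.392). In the parent psmA, a proteasome subunit gene, rose by 0.51 ± 0.15 and speB fell by 0.87 ± 0.18 (SE; adjusted p = 0.0165 and 0.00183). psmA did not pass without early log 2 (adjusted p = 0.116), stationary 2 (0.0533) or stationary 3 (0.0794), while speB passed in 4 of 4 such fits. speB is in no list and was chosen after its values were seen.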
